A study of Homo sapiens with 21 samples.

How the data were processed

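RNA was measured by sequencing of libraries made with ScriptSeq from total RNA of A673 cells. Per the labels, 2.5 ug of RNA were used per library, RNA was taken with Qiagen RNeasy and on-column DNase treatment, and cells were selected for 4 days before infection with the rescue vector. The groups are control RNAi (replicates 1, 2, 3 and 5), EWS/FLI RNAi with an empty vector (1 to 5), with wild-type type IV EWS/FLI (1 to 5), with delta 22 (1 to 4) and with mut9 (3 to 5). The replicate number is the labelled batch. The processing notes of the authors name bcl2fastq, STAR 2.5.2b, HTSeq, DESeq2 and the hg19 build.

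The deposited table holds normalized log2 values made by the authors, whose form is that of regularized logarithms: values from -4.1 to 20.2, low genes drawn together and 17358 genes at exactly 0. Since the values were already log2, no pseudocount was added and no further logarithm taken, and the filter on low values was moved to the log2 scale. These are changes from the design, which was otherwise written before the data were examined, as were the groups, the alternatives and the rule for named genes. Library totals and whole reads are not kept. Ensembl IDs were joined to names from GENCODE 29, with 51996 matched and 5824 not matched. All columns of values were used. The highest correlation between libraries was 0.9978, with 0 genes identical in that pair (a comparison of values, not a test).

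A gene was tested when at least 3 libraries reached 10 on the linear scale (18040 genes, 16488 with a symbol). A model with 1 mean per group was fitted to all 21 libraries with limma 3.58.1 (trend) in R 4.3.3, and adjusted p is the limma value after Benjamini-Hochberg, 2-sided, over all genes tested, called below 0.05. Genes near-identical to others can share reads, which was not measured, and are uncertain: the GSTM family, histones, ribosomal proteins and mitochondrial genes. FLI1 and EWSR1 were also tested by exact permutation of libraries between groups. The 2-sided p is 2 times the smaller 1-sided p, adjusted over 16 tests. This definition replaced the absolute difference after the first results were seen, and gives larger p.

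Gene lists, 29 in number, were written from general knowledge before values were examined, with membership not checked against a source: EWS/FLI-activated, EWS/FLI-repressed, GGAA-repeat, collagen and matrix, focal adhesion and integrin, actin and SRF/YAP targets, mesenchymal, TGF-beta, interferon, NF-kB, neural, ribosomal protein, DNA replication, histone, cell cycle, cholesterol, ATF4 and unfolded protein, Wnt, hedgehog, insulin-like growth factor, FOXO, endothelial, epithelial, glutathione, p53, hypoxia, immune, mitochondrial and housekeeping genes. The first pair of lists comes partly from work in A673. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists of a comparison. Camera values with a library left out, with a replicate block or for other splits are at the preset correlation only.

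Genes are named by rule: FLI1 and EWSR1; per comparison the 6 largest rises and 6 largest falls among called genes with a mean of at least 100, a symbol and groups that do not overlap; per list 2 to 4 members with the smallest adjusted p; and a fixed set of 16 genes known from Ewing sarcoma. From these a selection is printed, and some genes are not reported here. Members that moved against their list, and the delta 22 examples counted singly, were chosen after their values were seen.

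Shared knockdown libraries were examined by simulation without effects (20 runs), by overlap expected for independent calls, and by dividing the knockdown libraries between effects. Held-out fractions used genes with at least a 2-fold change in batches 1 and 2, and the ratio of median changes in each of batches 3 to 5.

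Batch numbers were checked for pairing: over 34 pairs of libraries of different groups that share a number, deviations from the group mean correlated at 0.20 on average, against -0.05 for others, and 24 pairs were above 0.1. A replicate block gave 1292 genes for the delta 22 rescue in place of 811.

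Alternatives were no filter (40462 genes), a mean of at least 100 (12166 genes), rescaling by trimmed means (largest factor 0.024 log2), quantile scaling, a replicate block, the compared groups only, array weights, leaving out single libraries and the test fry. Added after the data were seen were fits in batches 3 to 5 only, list counts without wild-type replicate 3 and single list members of the delta 22 rescue without each library. Comparisons of the mut9 and delta 22 effects with control, with the knockdown libraries divided, were added then too. The methods were tried on simulated data: of added changes of log2 0.5, 1 and 2, 52.2%, 86.6% and 97% were found for the knockdown and 35.8%, 79.1% and 97% for mut9 against wild type. A list of 25 genes shifted by 0.3 was found, and a held-out fraction of 0.5 was returned as 0.5. The simulated genes were drawn independently and without batches, and the shares found come from 200 changed genes of 18040. Correlation between genes, pairing and changes in most genes were thus not tried. Tables and figures were made with Python 3.11.15. GGAA repeats near genes were not searched, since no genome sequence was at hand.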

Results

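The series holds RNA sequencing of the Ewing sarcoma cell line A673, in which the fusion gene EWS/FLI was lowered by RNA interference and replaced by different versions of itself. Its title asks what the EWS portion contributes to binding of GGAA repeats. There are 21 libraries in 5 groups: control RNAi against luciferase with an empty vector (n = 4), EWS/FLI RNAi with an empty vector (n = 5), and EWS/FLI RNAi with wild-type EWS/FLI (n = 5), with the delta 22 mutant (n = 4) or with the mut9 mutant (n = 3). The EWS/FLI RNAi libraries with an empty vector are called the knockdown libraries below, and the others the control, wild-type, delta 22 and mut9 libraries. The deposited table gives log2 values for 57820 genes, of which 17358 are 0 in every library. Library totals are not kept by these values, so reads per library cannot be given. Between 16708 and 17326 genes per library reached a value of 10 on the linear scale, and 18040 genes were tested.

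Effects are log2 differences between group means with their standard error, written as difference ± error, and adjusted p is the Benjamini-Hochberg value from limma over all genes tested, 2-sided. Genes are said to have risen or fallen only when that value was under 0.05. Counts of list members adjusted over the list alone are the same as those over all genes unless given. The p-values measure spread between these samples, which may be technical. The median residual standard deviation was 0.207 log2. The main axis of variation, 71.3% of the variance, ran from control libraries (scores -103.9 to -90.9) to knockdown libraries (73.3 to 91.6). Wild-type (-62.8 to -30.5) and mut9 libraries (-31.4 to -24.4) lay between, and delta 22 libraries (69.1 to 91.9) lay among the knockdown libraries. The second axis held 8.6%.

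FLI1, an ETS transcription factor gene whose 3' part is in the fusion, was measured at mean log2 11.64 (SD 0.06) in control, 9.77 (0.16) in knockdown, 10.47 (0.13) in wild-type, 11.27 (0.23) in delta 22 and 10.23 (0.15) in mut9 libraries. On the linear scale these means were 3183, 877.2, 1426, 2500 and 1205. FLI1 was 3.64-fold lower after knockdown (log2 -1.87, exact 2-sided permutation p = 0.0159, adjusted p = 0.0363) and rose with the wild-type construct by log2 0.70 (exact p = 0.00794, adjusted p = 0.0363) and with delta 22 by log2 1.5 (exact p = 0.0159, adjusted p = 0.0363). With mut9 the difference was log2 0.46 (exact p = 0.0357, the smallest possible for these group sizes, adjusted p = 0.0706, limma adjusted p = 0.00157). Delta 22 libraries held more FLI1 than wild-type libraries (log2 0.80, exact p = 0.0159, adjusted p = 0.0363), whereas the difference of mut9 from wild type did not pass the same test (log2 -0.24, exact p = 0.0714, adjusted p = 0.0879). Mut9 minus delta 22 was log2 -1.05 (exact p = 0.0571, the smallest possible). Wild-type libraries stayed below control libraries (log2 -1.16, exact p = 0.0159, adjusted p = 0.0363). These reads cannot be divided between the fusion transcript, an intact FLI1 transcript and the construct.

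EWSR1, which supplies the 5' part of the fusion, had mean log2 14.17 in control, 13.71 in knockdown, 13.92 in wild-type, 13.65 in delta 22 and 13.85 in mut9 libraries. It fell after knockdown by log2 0.46 (difference -0.46, exact p = 0.0159, adjusted p = 0.0363). Most of its reads can come from the intact allele. With the wild-type construct the difference from knockdown was log2 0.20 (exact p = 0.0397, adjusted p = 0.0706, limma adjusted p = 0.00904). It was log2 -0.06 with delta 22 (exact p = 0.27, limma adjusted p = 0.686) and log2 0.13 with mut9 (exact p = 0.107, limma adjusted p = 0.146), and neither passed.

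**Figure D1:**
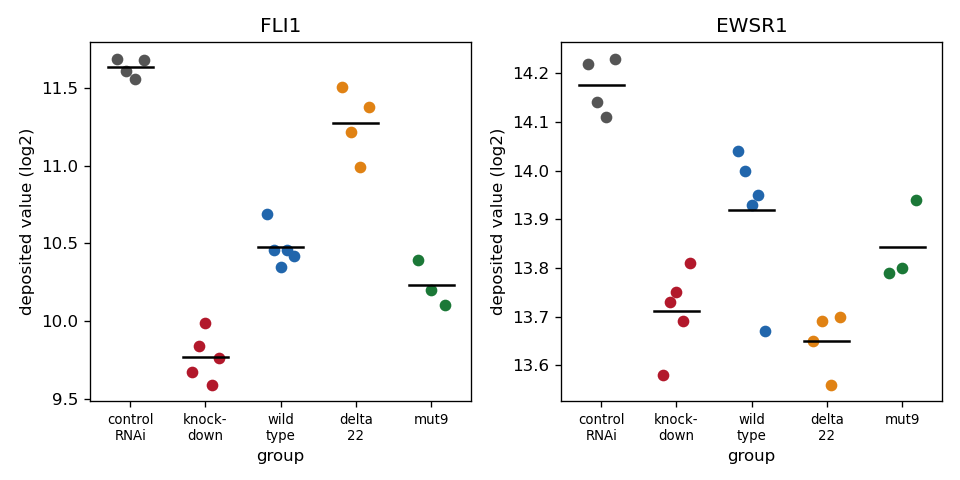
Log2 values of FLI1 and EWSR1 in each library, by group, with points for libraries and bars for group means. Delta 22 libraries have more FLI1 (mean 11.27) than wild-type (10.47) or mut9 libraries (10.23).

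The knockdown comparison asks which genes depend on EWS/FLI in A673 cells. Lowering EWS/FLI raised the cytokine gene LIF (log2 8.01 ± 0.51, 257-fold, adjusted p = 5.26e-11) and the insulin-like growth factor binding protein genes IGFBP3 (log2 7.72 ± 0.34, 211-fold, adjusted p = 3.5e-13) and IGFBP7 (log2 7.50 ± 0.16, 181-fold, adjusted p = 4.78e-17). It lowered PPP1R1A (log2 -5.56 ± 0.27, 47.2-fold, adjusted p = 1.2e-12), an inhibitor of protein phosphatase 1, and GLI1 (log2 -3.77 ± 0.19, 13.6-fold, adjusted p = 1.72e-12), the hedgehog pathway transcription factor (n = 5 and 4). In all, 12537 of 18040 genes changed, 6405 higher and 6132 lower, and 4735 changed at least 2-fold, 3197 of them higher. The groups did not overlap for 59.4% of genes, against 1.59% by chance. With quantile scaling the share of higher calls was 38% in place of 51.1%, and the median difference of all genes moved to -0.202, so the balance of rises and falls depends on scaling.

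Genes listed from general knowledge as EWS/FLI-activated, partly defined in this same cell line and not checked against a source, fell with knockdown (3 higher and 44 lower of 49, camera adjusted p = 3.84e-13, and adjusted p = 0.1 with an estimated correlation). Among them were KCNAB3 (-3.18 ± 0.16), a potassium channel subunit, FCGRT (-3.45 ± 0.20), the neonatal Fc receptor, LIPI (-4.64 ± 0.31), a lipase, and PRKCB (-3.64 ± 0.30), a protein kinase C. NR0B1 (-2.13 ± 0.26), an orphan nuclear receptor, NKX2-2 (-2.43 ± 0.16), a homeobox factor, STEAP1 (-1.51 ± 0.14) and CAV1 (-1.73 ± 0.13), the caveolin gene, fell as well. UPP1, PLD2 and PHF19 were the members that rose. Genes known for GGAA repeats near them moved the same way (1 higher and 18 lower of 20, camera adjusted p = 5.77e-08, and adjusted p = 0.1 with an estimated correlation). GSTM4 (-2.77 ± 0.19), a glutathione transferase, fell, but its reads can be shared with near-identical family members. SOX2 (log2 -0.62 ± 0.16) and the histone methyltransferase gene EZH2 (log2 -0.69 ± 0.09) fell by less, while the cyclin gene CCND1 did not pass (log2 0.04 ± 0.12, adjusted p = 0.768). Other large falls were SYNPR (-5.62 ± 0.35), AK7 (-5.37 ± 0.30), CLUL1 (-5.35 ± 0.38), POU1F1 (-5.21 ± 0.32), a pituitary transcription factor, and TSPAN8 (-5.18 ± 0.41), a tetraspanin.

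Genes listed in the same way as EWS/FLI-repressed rose (32 higher and 0 lower of 34, camera adjusted p = 3.84e-13, and adjusted p = 0.0996 with an estimated correlation), including LOX (5.88 ± 0.29), the lysyl oxidase, TGFBR2 (2.45 ± 0.18), a TGF-beta receptor, DKK1 (4.91 ± 0.25), a Wnt antagonist, and CDKN1A (2.88 ± 0.21), a cyclin-dependent kinase inhibitor. Genes of matrix and adhesion rose broadly. Collagen and matrix genes (37 higher and 2 lower of 40, camera adjusted p = 3.37e-11, and adjusted p = 0.1 with an estimated correlation) included COL6A1 (5.51 ± 0.24), COL6A2 (6.45 ± 0.25), LOXL2 (6.36 ± 0.27) and the fibronectin gene FN1 (2.84 ± 0.13). Focal adhesion and integrin genes (26 higher and 2 lower of 28) included ITGA3 (6.43 ± 0.25) and ITGA6 (3.66 ± 0.14). Actin and SRF/YAP target genes (28 higher and 0 lower of 30) included the tropomyosin gene TPM1 (4.13 ± 0.21) and AXL (5.66 ± 0.36), a receptor tyrosine kinase. Mesenchymal marker genes (17 higher and 2 lower of 20) included CD44 (6.46 ± 0.22), a hyaluronan receptor, and SNAI2 (4.22 ± 0.20). TGF-beta genes (17 higher and 1 lower of 19, camera adjusted p = 4.96e-07) included LTBP1 (5.26 ± 0.18) and SMAD3 (2.56 ± 0.13). PMP22 (7.62 ± 0.25), a myelin protein gene, and TNFSF15 (7.64 ± 0.44) were also among the largest rises. Neural marker genes fell more than they rose (5 higher and 12 lower of 19), with NPY1R (-3.77 ± 0.29) and ISL1 (-1.93 ± 0.11) lower. Camera adjusted p for these lists ran from 7.4e-10 (focal adhesion) to 0.00422 (neural markers). With an estimated correlation only the TGF-beta list passed (adjusted p = 0.0299), and the others had adjusted p = 0.0996 to 0.1.

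Interferon-response genes rose in every case (27 higher and 0 lower of 27, camera adjusted p = 3.11e-08, and adjusted p = 0.322 with an estimated correlation), for example IRF1 (4.27 ± 0.30), IFIT3 (4.96 ± 0.53) and XAF1 (7.58 ± 0.90). NF-kB and inflammation genes did too (21 higher and 0 lower of 21, camera adjusted p = 1.52e-07, and adjusted p = 0.287 with an estimated correlation), with the chemokine genes CXCL8 (6.61 ± 0.47) and CXCL1 (7.07 ± 0.56). Other lists fell after knockdown. DNA replication genes (1 higher and 27 lower of 30) included E2F2 (-2.30 ± 0.18), RFC4 (-1.01 ± 0.08) and POLE (-0.92 ± 0.08). Replication histone genes (0 higher and 14 lower of 14) and ribosomal protein genes (0 higher and 29 lower of 30) fell, both uncertain because reads can be shared with near-identical copies. RPS19 (-0.82 ± 0.07) was lower. Cholesterol synthesis genes fell (2 higher and 21 lower of 24). Cell cycle genes fell in part (0 higher and 16 lower of 29, adjusted over the list alone 0 and 14), with the cyclin gene CCNA2 (-0.94 ± 0.10). Unfolded protein and ATF4 target genes mostly rose (16 higher and 3 lower of 24). Camera adjusted p for the lists after NF-kB ran from 2.78e-09 (ribosomal proteins) to 0.0104 (ATF4 targets), and the lowest with an estimated correlation was adjusted p = 0.236 (ribosomal proteins). Statements on lists therefore rest on counts of members, which are not independent of each other. They are to be read beside the share of all genes called, here 6405 higher and 6132 lower of 18040. Members that moved against their list, chosen after their values were seen, included COL21A1 and DCN (collagen), CAV1 and CAV2 (focal adhesion), CDH11 and THY1 (mesenchymal), SMAD6 (TGF-beta), EGR2 (GGAA repeats), CCNE2 (DNA replication), and PSAT1, PHGDH and SLC7A5 (ATF4). Of the neural markers TUBB3, STMN2, NCAM1, GAP43 and NEFM rose.

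**Figure D2:**
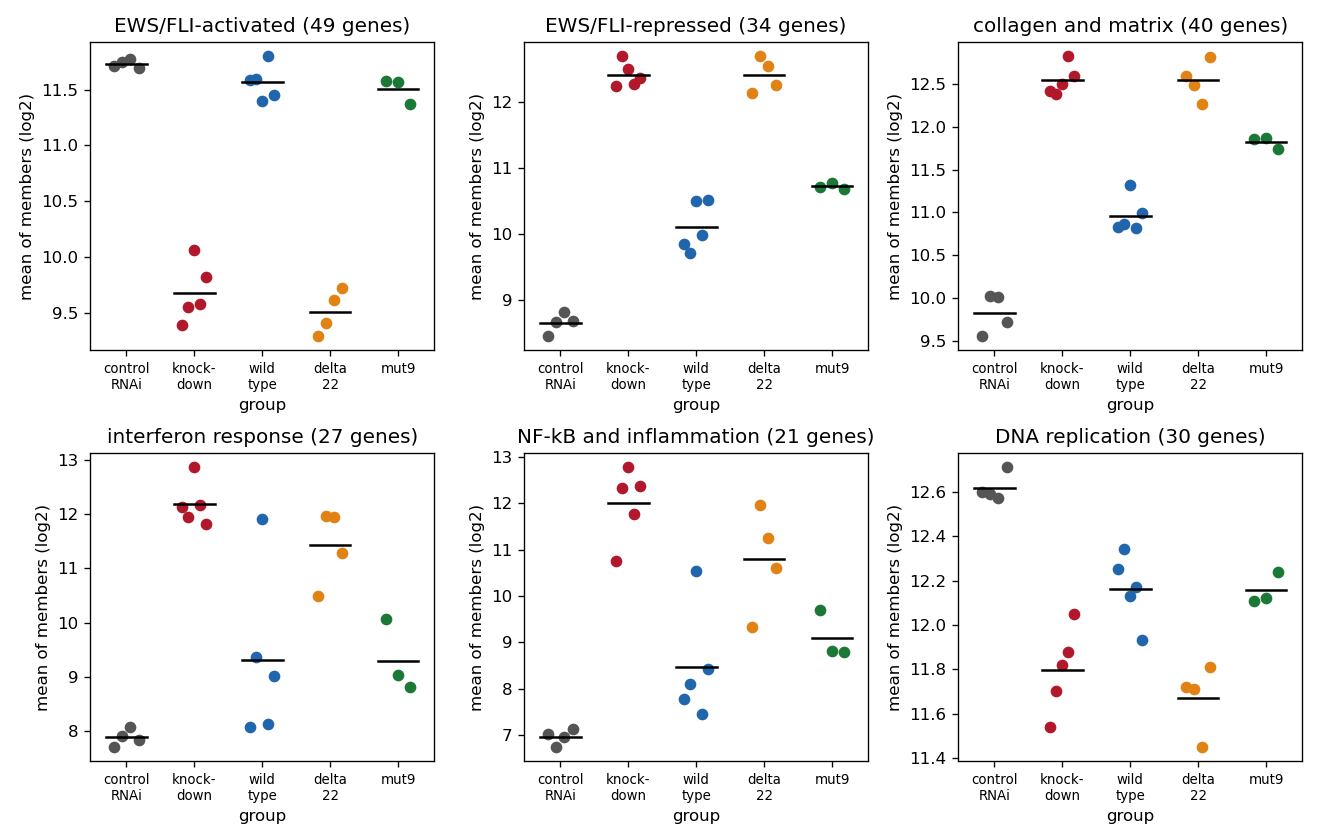
Mean log2 value of the members of 6 gene lists in each library, by group, with points for libraries and bars for group means. Activated genes are high in control, wild-type and mut9 libraries, and 1 wild-type library (replicate 3) is high for interferon (11.91) and NF-kB genes (10.54).

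The wild-type rescue asks which genes respond when intact EWS/FLI is put back. It raised APELA (log2 5.71 ± 0.28, 52.2-fold, adjusted p = 6.32e-12), an apelin receptor ligand. It lowered the matrix gene THBS1 (log2 -5.68 ± 0.38, 51.3-fold, adjusted p = 2.9e-10) and LIF (log2 -5.67 ± 0.48, 50.9-fold, adjusted p = 5.79e-09) (n = 5 and 5). Of 18040 genes, 11154 changed, 5334 higher and 5820 lower, with 3523 at least 2-fold, 1220 higher and 2303 lower. Groups did not overlap for 42.5% of genes (0.79% by chance). With quantile scaling 59.5% of calls were higher in place of 47.8%, the median of all genes moved to 0.12, and GAPDH, a glycolytic gene often used as reference, went from log2 -0.32 ± 0.07 to 0.08.

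Activated genes came back (42 higher and 4 lower of 49, adjusted over the list alone 43 and 4, camera adjusted p = 1.37e-15, and adjusted p = 0.0812 with an estimated correlation), among them NR0B1 (1.96 ± 0.24), PRKCB (3.54 ± 0.28), NKX2-2 (2.31 ± 0.16), GLI1 (2.76 ± 0.17), GSTM4 (2.38 ± 0.18), CAV1 (1.18 ± 0.12), STEAP1 (1.54 ± 0.13), FCGRT (3.28 ± 0.19), LOXHD1 (4.47 ± 0.25) and the growth factor gene IGF1 (4.40 ± 0.25). The members that fell were KIT, UPP1, PLD2 and PHF19. GGAA-repeat genes rose (18 higher and 1 lower of 20, camera adjusted p = 4.59e-10, and adjusted p = 0.0812 with an estimated correlation). CCND1 (log2 0.20 ± 0.11, adjusted p = 0.114) and the forkhead gene FOXO1 (log2 -0.35 ± 0.19, adjusted p = 0.111) did not pass, though CCND1 did without wild-type replicate 1 (0.26) and with quantile scaling (0.61). Repressed genes fell (1 higher and 30 lower of 34, camera adjusted p = 1.48e-10, and adjusted p = 0.0812 with an estimated correlation), including IGFBP3 (-4.90 ± 0.32), LOX (-3.41 ± 0.27), TGFBR2 (-1.70 ± 0.17) and CD44 (-3.23 ± 0.20). TSC22D3 was the repressed member that rose. Collagen and matrix genes fell (2 higher and 34 lower of 40), with COL6A1 (-4.18 ± 0.23), COL6A2 (-4.22 ± 0.23) and FN1 (-1.78 ± 0.13). So did focal adhesion genes (2 higher and 24 lower of 28; ITGA3 (-4.20 ± 0.24)), actin and SRF/YAP targets (0 higher and 28 lower of 30, adjusted over the list alone 0 and 29; TPM1 (-2.80 ± 0.19)), TGF-beta genes (1 higher and 15 lower of 19) and mesenchymal markers (2 higher and 14 lower of 20, adjusted over the list alone 2 and 15, and 4 higher under quantile scaling). Neural markers rose (13 higher and 3 lower of 19). COL21A1, DCN, CAV1, CAV2, SMAD6 and THY1 again moved against their lists, now upward. Camera adjusted p for the lists of this paragraph after the repressed genes ran from 2.59e-09 (collagen and actin targets) to 0.000208 (neural markers), and none passed with an estimated correlation (lowest adjusted p = 0.0557, TGF-beta).

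Interferon genes (0 higher and 27 lower of 27) and NF-kB genes (0 higher and 21 lower of 21) fell with the wild-type construct, for example IRF1 (-2.99 ± 0.28), CXCL8 (-4.26 ± 0.44), CXCL1 (-5.11 ± 0.53) and XAF1 (-5.49 ± 0.85). The osteopontin gene SPP1 (-5.44 ± 0.28), which is in neither list, was also among the largest falls. Wild-type replicate 3 stood apart with a mean of 11.91 over the interferon list against 8.08 to 9.37 in the other wild-type libraries and 11.81 to 12.86 after knockdown. For the NF-kB list it had 10.54 against 7.46 to 8.43. DNA replication genes rose (22 higher and 1 lower of 30), with E2F2 (1.80 ± 0.17) and POLE (0.77 ± 0.08). Histone genes (8 higher and 0 lower of 14) and ribosomal protein genes (12 higher and 0 lower of 30) came back in part, the latter with 23 members higher under quantile scaling. ATF4 targets fell (0 higher and 18 lower of 24, adjusted over the list alone 1 and 18). Cholesterol synthesis (7 higher and 3 lower of 24, adjusted over the list alone 6 and 3, camera adjusted p = 0.272) and cell cycle genes (5 higher and 3 lower of 29, adjusted over the list alone 4 and 3, camera adjusted p = 0.499) gave no list result, with 12 and 10 members higher under quantile scaling. Camera adjusted p was 5.55e-07 for interferon, 5.58e-07 for NF-kB, 0.000114 for DNA replication, 0.0294 for histone, 0.0324 for ribosomal protein and 0.000328 for ATF4 genes. With an estimated correlation the lowest was adjusted p = 0.354 (NF-kB). The histone call was lost without knockdown replicate 1 (0.0554) or wild-type replicate 2 (0.0514), and the ribosomal call without knockdown replicate 1 (0.0649) or 2 (0.0648) or wild-type replicate 1 (0.12).

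Wild-type against control libraries asks how far the rescue falls short of the starting state. The myelin gene PMP22 (log2 4.78 ± 0.25, 27.5-fold, adjusted p = 1.1e-10) and CD44 (log2 3.23 ± 0.22, 9.41-fold, adjusted p = 3.72e-09) remained above control, while the telomerase gene TERT (log2 -2.70 ± 0.30, 6.51-fold, adjusted p = 1.23e-06) and the receptor gene KIT (log2 -2.19 ± 0.27, 4.56-fold, adjusted p = 5e-06) remained below it (n = 5 and 4). There were 7135 genes that differed, 3834 higher and 3301 lower, with 1423 at least 2-fold, 1109 of them higher. Quantile scaling gave 42.7% of calls higher in place of 53.7%. Activated genes were near control (6 higher and 11 lower of 49, adjusted over the list alone 6 and 9, camera adjusted p = 0.0944): NR0B1 (log2 -0.17 ± 0.26, adjusted p = 0.618), NKX2-2 (log2 -0.12 ± 0.16, adjusted p = 0.584), PRKCB (log2 -0.10 ± 0.30, adjusted p = 0.818) and STEAP1 (log2 0.03 ± 0.14, adjusted p = 0.895) did not pass. Without wild-type replicate 4 the activated list had camera adjusted p = 0.023. GLI1 (-1.01 ± 0.19) and PPP1R1A (-1.89 ± 0.27) stayed lower and IGF1 (1.92 ± 0.27) higher. Repressed genes stayed high (29 higher and 0 lower of 34, adjusted over the list alone 30 and 0, camera adjusted p = 3.76e-11, and adjusted p = 0.112 with an estimated correlation), with IGFBP7 (3.29 ± 0.16), IGFBP3 (2.82 ± 0.34) and LOX (2.47 ± 0.29). Collagen (24 higher and 2 lower of 40; LOXL2 (3.19 ± 0.27)), focal adhesion (23 higher and 1 lower of 28), TGF-beta (13 higher and 0 lower of 19, adjusted over the list alone 14 and 0) and mesenchymal genes (13 higher and 0 lower of 20, adjusted over the list alone 14 and 1) stayed high too, as did, in part, actin targets (15 higher and 0 lower of 30, adjusted over the list alone 16 and 0). COL4A1 and FBN2 were the collagen-list genes below control. Camera adjusted p for these ran from 6.86e-08 (collagen) to 0.00127 (actin targets), with lowest adjusted p = 0.0581 with an estimated correlation (TGF-beta). Insulin-like growth factor genes were higher (10 higher and 0 lower of 16, camera adjusted p = 0.000117), a result kept at adjusted p = 0.0246 with an estimated correlation.

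Other lists stayed below control in wild-type libraries. These were ribosomal protein genes (0 higher and 29 lower of 30; RPS19 (-0.58 ± 0.07), RPLP0 (-0.59 ± 0.07)), DNA replication genes (0 higher and 25 lower of 30, adjusted over the list alone 0 and 26; PCNA (-1.05 ± 0.12)), histone genes (0 higher and 14 lower of 14), cholesterol genes (0 higher and 18 lower of 24, adjusted over the list alone 0 and 19) and, in part, cell cycle genes (0 higher and 14 lower of 29, and 9 lower under quantile scaling). Interferon (13 higher and 0 lower of 27) and NF-kB genes (10 higher and 0 lower of 21, adjusted over the list alone 11 and 0) stayed above control in part. Without wild-type replicate 3, the library that stood apart for these lists, 11 and 6 members were higher. Camera adjusted p was 4.5e-16 for ribosomal protein genes, 3.16e-10 for DNA replication, 9.86e-08 for histone, 7.5e-07 for cholesterol, 3.03e-05 for cell cycle, 0.000172 for interferon and 0.00112 for NF-kB genes. The lowest with an estimated correlation was adjusted p = 0.174 (ribosomal protein genes).

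The delta 22 rescue asks whether this mutant can replace EWS/FLI. FLI1 itself rose 2.84-fold, yet the activated genes did not come back: PRKCB (log2 -0.37 ± 0.30, adjusted p = 0.559), GLI1 (log2 0.05 ± 0.19, adjusted p = 0.92), NKX2-2 (log2 0.20 ± 0.16, adjusted p = 0.561) and GSTM4 (log2 -0.34 ± 0.19, adjusted p = 0.336) did not pass. The binding protein gene IGFBP5 (log2 2.28 ± 0.23, 4.86-fold, adjusted p = 3.51e-05) and the prohormone convertase gene PCSK1 (log2 1.83 ± 0.23, 3.56-fold, adjusted p = 0.000248) rose. SPX (log2 -3.29 ± 0.53, 9.75-fold, adjusted p = 0.00161), a neuropeptide gene, and the asparagine synthetase gene ASNS (log2 -1.45 ± 0.18, 2.74-fold, adjusted p = 0.000203) fell (n = 4 and 5). In all, 811 genes changed, 404 higher and 407 lower, with 198 at least 2-fold, 68 higher and 130 lower. The count was 1292 with a replicate block, 640 higher and 652 lower, and 262 in a fit of the compared groups only. Leaving out delta 22 replicate 1 gave 383, replicate 2 gave 502 and replicate 4 gave 484, and leaving out knockdown replicate 5 gave 495. Groups did not overlap for 8.4% of genes (1.59% by chance).

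Activated genes showed 0 higher and 2 lower of 49, adjusted over the list alone 0 and 3, camera adjusted p = 0.138 with delta 22, the members being NR0B1 (log2 -1.07 ± 0.26) and FEZF1 (log2 -1.11 ± 0.26), which moved down, away from control. Repressed genes showed 3 higher and 0 lower of 34, camera adjusted p = 0.794: IGFBP5, DKK1 (1.03 ± 0.25) and ITGB3 (1.18 ± 0.27) moved up. NR0B1 lost its call without knockdown replicate 5 (-0.97) or delta 22 replicate 1 (-0.88), and FEZF1 without delta 22 replicate 1 (-0.93) or 2 (-1.02). DKK1 lost it without knockdown replicate 3 (0.91) or 5 (0.97) or delta 22 replicate 2 (1.03) or 4 (0.95). The activated list itself had camera adjusted p = 0.0114 without knockdown replicate 1 and 0.0116 without delta 22 replicate 4. GGAA-repeat genes gave 0 higher and 1 lower of 20, again NR0B1 (camera adjusted p = 0.395). Of 40 collagen genes limma called 0, with 6 at an unadjusted p under 0.05 (camera adjusted p = 0.925). IGFBP3 (log2 0.27 ± 0.34, adjusted p = 0.725), LOX (log2 -0.42 ± 0.29, adjusted p = 0.46) and FN1 (log2 0.10 ± 0.13, adjusted p = 0.745) did not pass. ATF4 targets were the list with the most members called (0 higher and 8 lower of 24, adjusted over the list alone 0 and 16, camera adjusted p = 3.42e-14, and adjusted p = 0.403 with an estimated correlation): ASNS (-1.45 ± 0.18), TRIB3 (-1.70 ± 0.30), CHAC1 (-1.24 ± 0.24) and SESN2 (-1.45 ± 0.28) fell. Other rises were SEMA3D (1.60 ± 0.16), a semaphorin, and CRYAB (1.63 ± 0.31), a small heat shock protein; other falls were CA12 (-1.98 ± 0.35), a carbonic anhydrase, and HKDC1 (-1.89 ± 0.32). Interferon genes had a median of log2 -0.74 (camera adjusted p = 0.000703, and adjusted p = 0.886 with an estimated correlation), and limma called 0 of 27, with 2 at an unadjusted p under 0.05. NF-kB genes had a median of log2 -1.10 (camera adjusted p = 9.28e-07, and adjusted p = 0.791 with an estimated correlation), and limma called 0 of 21, with 11 at an unadjusted p under 0.05 and 4 called lower without wild-type replicate 3, the library with the high mean for this list (10.54). By batch, 1 to 4, the NF-kB mean was 9.33, 11.96, 11.26 and 10.61 with delta 22 and 10.76, 12.34, 12.78 and 11.77 after knockdown. The interferon mean was not lower in batch 2 (11.97 against 11.94).

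Other lists passed camera with delta 22 on few members, named after their values were seen. Focal adhesion genes (1 higher and 0 lower of 28, adjusted over the list alone 6 and 0, camera adjusted p = 0.00876) had ITGB3, DNA replication genes (0 higher and 1 lower of 30, adjusted over the list alone 0 and 0, camera adjusted p = 0.00541) had RFC4 (-0.30 ± 0.08), and histone genes (0 higher and 1 lower of 14, camera adjusted p = 0.00972) had H2AC6 (-0.41 ± 0.10). Of 29 cell cycle genes limma called 0, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0489, and 0.249 with a replicate block). None passed with an estimated correlation (lowest adjusted p = 0.791). The cell cycle call was lost without knockdown replicate 2 (0.091), 3 (0.0862) or 5 (0.511) or delta 22 replicate 1 (0.505). The DNA replication and histone calls were lost without knockdown replicate 5 (0.167 and 0.148) or delta 22 replicate 3 (0.365 and 0.584). RFC4 lost its call without knockdown replicate 3 (-0.28), 4 (-0.26) or 5 (-0.26) or delta 22 replicate 1 (-0.29), 2 (-0.29) or 3 (-0.25), and H2AC6 without knockdown replicate 5 (-0.37) or delta 22 replicate 1 (-0.41) or 3 (-0.34).

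Delta 22 against wild type asks directly how far the mutant differs from the intact protein. THBS1 (log2 6.35 ± 0.41, 81.8-fold, adjusted p = 1.74e-10) and PDGFRA (log2 5.35 ± 0.29, 40.7-fold, adjusted p = 2.72e-11), a growth factor receptor, were higher, and APELA (log2 -6.20 ± 0.30, 73.3-fold, adjusted p = 6.07e-12) and IGF1 (log2 -5.19 ± 0.27, 36.5-fold, adjusted p = 1.38e-11) lower (n = 4 and 5). There were 11045 calls, 5727 higher and 5318 lower, 3561 of them at least 2-fold. Quantile scaling gave 41.9% of calls higher in place of 51.9%, with GAPDH going from log2 0.59 ± 0.08 to -0.02. Activated genes were lower (4 higher and 43 lower of 49, camera adjusted p = 8.64e-16, and adjusted p = 0.0841 with an estimated correlation), among them NR0B1 (-3.03 ± 0.26), PRKCB (-3.91 ± 0.30), GLI1 (-2.71 ± 0.19), GSTM4 (-2.72 ± 0.19) and LOXHD1 (-5.21 ± 0.27). Repressed genes were higher (30 higher and 2 lower of 34, camera adjusted p = 4.31e-10, and adjusted p = 0.0841 with an estimated correlation), with IGFBP3 (5.16 ± 0.34) and LOX (2.98 ± 0.29). Lists that were higher were collagen (35 higher and 2 lower of 40), focal adhesion (25 higher and 2 lower of 28), actin targets (27 higher and 0 lower of 30), TGF-beta (16 higher and 1 lower of 19), interferon (25 higher and 0 lower of 27) and NF-kB (19 higher and 0 lower of 21). DNA replication (1 higher and 22 lower of 30, adjusted over the list alone 1 and 24) and histone genes (0 higher and 11 lower of 14) were lower, and ribosomal protein genes gave 0 higher and 9 lower of 30, adjusted over the list alone 0 and 7, without a list result (26 lower under quantile scaling). The camera adjusted p of these lists ran from 9.5e-10 for focal adhesion to 0.0732 for ribosomal proteins, and none passed with an estimated correlation (lowest adjusted p = 0.0505, TGF-beta). The ribosomal list passed without wild-type replicate 3 (0.0338) or 5 (0.0268) or delta 22 replicate 4 (0.0381).

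The mut9 rescue asks the same of the other mutant. It raised APELA (log2 5.87 ± 0.32, 58.6-fold, adjusted p = 1.21e-10), ISM2 (log2 5.88 ± 0.36, 58.8-fold, adjusted p = 3.78e-10), a secreted protein, and FCGRT (log2 4.17 ± 0.22, 18-fold, adjusted p = 8.9e-11), and lowered LIF (log2 -4.71 ± 0.55, 26.1-fold, adjusted p = 1.07e-06) and IGFBP3 (log2 -3.08 ± 0.36, 8.47-fold, adjusted p = 1.2e-06) (n = 3 and 5). There were 8759 changes, 4151 higher and 4608 lower, with 3032 at least 2-fold, 1198 higher and 1834 lower, and groups did not overlap for 46.9% of genes (3.57% by chance). Activated genes rose (41 higher and 2 lower of 49, adjusted over the list alone 43 and 2, camera adjusted p = 1.62e-18, and adjusted p = 0.0794 with an estimated correlation), with NR0B1 (2.61 ± 0.28), PRKCB (3.94 ± 0.33), NKX2-2 (2.66 ± 0.18), GLI1 (2.18 ± 0.20), GSTM4 (3.61 ± 0.20), STEAP1 (1.29 ± 0.15), CAV1 (1.02 ± 0.14), IGF1 (4.73 ± 0.29) and LOXHD1 (4.57 ± 0.29). CCND1 (0.47 ± 0.13) rose as well. GGAA-repeat genes rose (18 higher and 0 lower of 20, adjusted over the list alone 19 and 0, camera adjusted p = 2.67e-11, and adjusted p = 0.0819 with an estimated correlation) and so did neural markers (10 higher and 3 lower of 19, adjusted over the list alone 12 and 3). Repressed genes fell (1 higher and 25 lower of 34, camera adjusted p = 2.18e-09, and adjusted p = 0.0971 with an estimated correlation), with LOX (-2.59 ± 0.31), while FOXO1 did not pass (log2 -0.09 ± 0.22, adjusted p = 0.748).

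Matrix genes also fell with mut9. The collagen list gave 2 higher and 25 lower of 40, adjusted over the list alone 3 and 26, camera adjusted p = 0.000328, and adjusted p = 0.451 with an estimated correlation, with COL6A1 (-2.0 ± 0.26), COL6A2 (-2.11 ± 0.27) and, going up, COL21A1 (3.72 ± 0.30). Focal adhesion genes (2 higher and 21 lower of 28, adjusted over the list alone 2 and 23; ITGA2 (-4.43 ± 0.38)), actin targets (1 higher and 25 lower of 30, adjusted over the list alone 1 and 27), TGF-beta genes (1 higher and 12 lower of 19) and mesenchymal markers (3 higher and 12 lower of 20) fell. Interferon genes (0 higher and 25 lower of 27, adjusted over the list alone 0 and 26) and NF-kB genes (0 higher and 19 lower of 21, adjusted over the list alone 0 and 21) fell, among them MX2 (-6.29 ± 1.03), OAS2 (-5.24 ± 0.99), IFI27 (-5.63 ± 1.06) and CXCL8 (-3.29 ± 0.51). DNA replication genes (21 higher and 0 lower of 30, adjusted over the list alone 22 and 0) rose, and histone (6 higher and 0 lower of 14) and cholesterol genes (11 higher and 1 lower of 24, camera adjusted p = 0.00901, and adjusted p = 0.671 with an estimated correlation) did so in part. Quantile scaling gave 10 histone genes, 4 collagen genes and 5 ATF4 targets higher. Camera adjusted p for the lists from focal adhesion to histone genes ran from 1.08e-08 (actin targets) to 0.0138 (histone genes). With an estimated correlation the lowest was adjusted p = 0.0794 (TGF-beta and neural genes). The cholesterol list had adjusted p = 0.0561 without mut9 replicate 3. ATF4 targets fell in part (0 higher and 12 lower of 24, camera adjusted p = 0.0176, and adjusted p = 0.606 with an estimated correlation), with adjusted p = 0.067 without mut9 replicate 4. Ribosomal protein genes showed 5 higher and 0 lower of 30, adjusted over the list alone 0 and 0, camera adjusted p = 0.193, and 19 members were higher under quantile scaling.

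Mut9 against wild type asks what this mutant leaves undone. Collagen VI genes stayed higher with mut9, COL6A1 (log2 2.18 ± 0.26, 4.52-fold, adjusted p = 3.87e-05) and COL6A2 (log2 2.11 ± 0.27, 4.32-fold, adjusted p = 6.69e-05), as did IGFBP7 (log2 2.57 ± 0.18, 5.95-fold, adjusted p = 4.7e-08). The neuropeptide genes CALCB (log2 -3.69 ± 0.31, 12.9-fold, adjusted p = 8.58e-07) and CCK (log2 -3.25 ± 0.46, 9.48-fold, adjusted p = 0.000146) were lower (n = 3 and 5). There were 3390 calls, 2018 higher and 1372 lower, with 610 at least 2-fold, 476 of them higher. The count was 1723 without mut9 replicate 3, 1903 without mut9 replicate 4, 5234 with array weights and 1745 in batches 3 to 5 only. Groups did not overlap for 23.8% of genes (3.57% by chance). Quantile scaling gave 43.9% of calls higher in place of 59.5%, so the direction of the surplus is not settled.

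Collagen and matrix genes formed the largest set that was higher (24 higher and 0 lower of 40, adjusted over the list alone 30 and 1, camera adjusted p = 3.28e-11, and adjusted p = 0.185 with an estimated correlation), with P4HA2 (1.70 ± 0.23), a prolyl hydroxylase, and FN1 (1.04 ± 0.15). Focal adhesion genes (13 higher and 1 lower of 28) included LAMA4 (2.65 ± 0.36) and ITGB1 (0.59 ± 0.09). Insulin-like growth factor genes (6 higher and 0 lower of 16, adjusted over the list alone 8 and 0) included IGFBP5 (1.93 ± 0.25) and IGFBP6 (1.23 ± 0.20), and mesenchymal markers (9 higher and 2 lower of 20) included PDGFRA (2.47 ± 0.32) and SPARC (1.14 ± 0.21). Camera adjusted p for these lists was 2.74e-05, 0.00193 and 0.00175, with lowest adjusted p = 0.0824 with an estimated correlation (growth factor genes). Other large differences were CFI (3.59 ± 0.43), a complement factor, MATN2 (2.77 ± 0.37), a matrix protein, and TM4SF1 (2.74 ± 0.26) higher, and DACT2 (-2.15 ± 0.37) lower. FRG2FP, a pseudogene that can share reads with its relatives, was log2 -2.40 ± 0.48. Activated genes gave no list result (6 higher and 4 lower of 49, adjusted over the list alone 6 and 6, camera adjusted p = 0.772): NR0B1 (log2 0.65 ± 0.28, adjusted p = 0.111), PRKCB (log2 0.40 ± 0.33, adjusted p = 0.426), NKX2-2 (log2 0.35 ± 0.18, adjusted p = 0.194) and GLI1 (log2 -0.58 ± 0.20, adjusted p = 0.0513) did not pass, while GSTM4 (1.22 ± 0.20) was higher. CALCB (-3.69 ± 0.31) and CCK (-3.25 ± 0.46), given above among the largest falls, were among the lower activated members, and CALCB is also in the GGAA-repeat list. Quantile scaling gave 7 activated genes lower. GLI1 passed without wild-type replicate 2 (-0.63) or 5 (-0.64). GGAA-repeat genes gave 2 higher and 3 lower of 20, adjusted over the list alone 2 and 4, camera adjusted p = 0.506. Repressed genes were higher in part (13 higher and 2 lower of 34, adjusted over the list alone 15 and 2, camera adjusted p = 0.00193, and adjusted p = 0.561 with an estimated correlation), with CD44 (1.21 ± 0.23), and ZYX and HMGA2 as the lower members. LOX did not pass (log2 0.82 ± 0.31, adjusted p = 0.0738), but did without wild-type replicate 5 (1.01) or mut9 replicate 3 (1.1).

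Interferon genes (0 higher and 0 lower of 27) and NF-kB genes (2 higher and 0 lower of 21, adjusted over the list alone 1 and 0) gave few calls between mut9 and wild-type libraries. At an unadjusted p under 0.05, limma had 2 and 4 of them. Without wild-type replicate 3, the library with the high interferon (11.91) and NF-kB (10.54) means, 5 and 8 members were higher (camera adjusted p = 0.00423 and 0.00041). No correlation was estimated for this fit. Mut9 replicate 3, the highest mut9 library for both lists (10.06 and 9.7), stayed in without its batch partner. In batches 4 and 5 interferon means were 9.03 and 8.81 with mut9 and 8.14 and 9.02 with wild type, so the direction differed. The NF-kB means were 8.81 and 8.79 against 7.46 and 8.43. ATF4 targets were higher in part (7 higher and 0 lower of 24, adjusted over the list alone 8 and 1, camera adjusted p = 0.0271, and adjusted p = 0.727 with an estimated correlation). That call was lost without wild-type replicate 4 (0.0807) or 5 (0.156) or mut9 replicate 3 (0.232). Actin targets (7 higher and 1 lower of 30, camera adjusted p = 0.0271, and adjusted p = 0.727 with an estimated correlation) lost the call with a replicate block (adjusted p = 0.0819) and without wild-type replicate 2 (0.105) or 4 (0.105) or mut9 replicate 5 (0.147). TGF-beta genes (5 higher and 0 lower of 19, camera adjusted p = 0.0524) gained one with the block (adjusted p = 0.043) and without wild-type replicate 1 (0.0412) or 5 (0.0277) or mut9 replicate 3 (0.019).

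Mut9 against delta 22 asks whether the mutants differ from each other. APELA (log2 6.36 ± 0.34, 82.2-fold, adjusted p = 1.21e-10) and IGF1 (log2 5.53 ± 0.31, 46.1-fold, adjusted p = 1.75e-10) were higher and THBD (log2 -5.15 ± 0.50, 35.5-fold, adjusted p = 1.16e-07), the thrombomodulin gene, lower with mut9 (n = 3 and 4). There were 8885 calls, 4229 higher and 4656 lower, 2956 of them at least 2-fold. Activated genes (41 higher and 2 lower of 49, adjusted over the list alone 42 and 2; NR0B1 (3.68 ± 0.29), GSTM4 (3.94 ± 0.21), PRKCB (4.31 ± 0.34)) and GGAA-repeat genes (18 higher and 0 lower of 20) were higher. Lower were repressed genes (1 higher and 25 lower of 34, adjusted over the list alone 1 and 26), focal adhesion (2 higher and 24 lower of 28, adjusted over the list alone 2 and 25), actin target (0 higher and 26 lower of 30, adjusted over the list alone 0 and 27), collagen (2 higher and 22 lower of 40) and interferon genes (0 higher and 22 lower of 27). NF-kB genes showed 0 higher and 8 lower of 21, 15 members lower with a replicate block and 14 without wild-type replicate 3. DNA replication genes were higher (23 higher and 0 lower of 30). Camera adjusted p ran from 5.36e-19 (activated genes) to 0.00416 (NF-kB), and none passed with an estimated correlation (lowest adjusted p = 0.0964, activated genes).

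**Figure D3:**
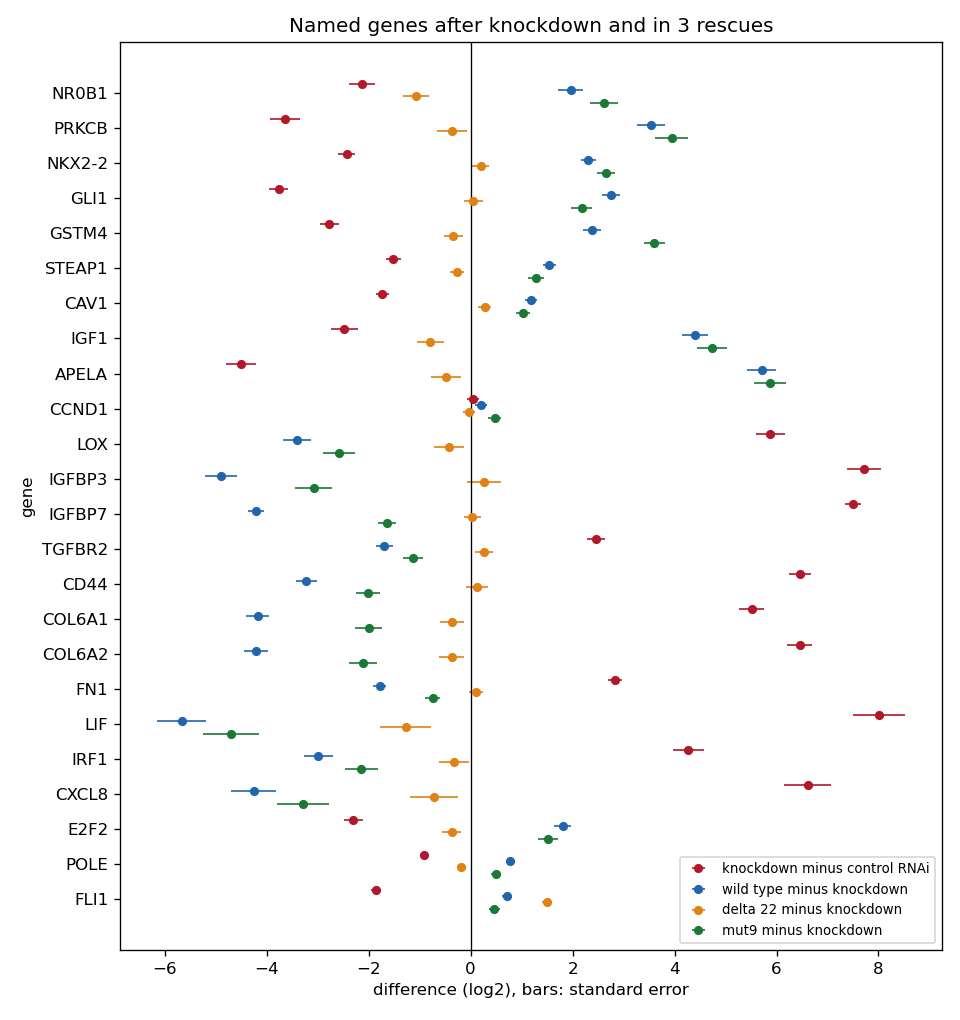
Log2 differences with standard errors of 24 named genes in the knockdown and in the 3 rescues against knockdown libraries. PRKCB falls after knockdown (-3.64) and rises with wild type (3.54) and mut9 (3.94), and does not pass with delta 22 (-0.37).

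Gene sets were then followed across the rescues. Of 5334 genes raised by wild-type EWS/FLI, among them PRKCB and NKX2-2, 3393 (63.6%) also rose with mut9 and 109 (2%) with delta 22. Delta 22 moved 72 of them the other way. Against wild type, 4463 (83.7%) were weaker with delta 22, 977 (18.3%) weaker with mut9 and 237 (4.4%) stronger with mut9. Of 5820 genes lowered by wild type, among them LOX and IGFBP3, 4009 (68.9%) also fell with mut9 and 209 (3.6%) with delta 22, which raised 177. In this class 4982 (85.6%) were weaker with delta 22 and 1397 (24%) with mut9. The median log2 change of the activated class was 0.52 with wild type, 0.40 with mut9 and 0.01 with delta 22, and of the repressed class -0.79, -0.57 and 0. The classes were picked with the same wild-type libraries, so part of the surplus of weaker genes and of the gap between medians can come from the selection, which the held-out fractions avoid. Activated genes shared with delta 22 were 194 with a replicate block, 56 without a filter and 28 from the compared groups only, and repressed ones 352 with a block, 138 at a mean of at least 100 and 97 from the compared groups only. With quantile scaling 1660 activated genes were weaker with mut9. The counts weaker with mut9 were 513 activated and 788 repressed without mut9 replicate 3, and 556 and 871 without mut9 replicate 4. Counts shared with delta 22 ranged from 53 to 122 activated and from 119 to 290 repressed as single libraries were left out. The lowest of both were without delta 22 replicate 1, 131 repressed genes were shared without delta 22 replicate 4, and 64, 66 and 58 activated genes were shared without knockdown replicate 5, delta 22 replicate 2 and delta 22 replicate 4.

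Seen from the knockdown, 4276 (69.7%) of the 6132 genes that had fallen, such as NR0B1 and GLI1, rose with wild type, 3399 (55.4%) with mut9 and 90 (1.5%) with delta 22, which lowered 96 further. Of the 6405 that had risen, such as LIF and CD44, 5023 (78.4%) fell with wild type, 4050 (63.2%) with mut9 and 206 (3.2%) with delta 22, which raised 213 further. The knockdown libraries stand on both sides of these counts, which favours moves back. For genes that fell and rose again, independent calls would give 1813 with wild type, 1411 with mut9 and 137 with delta 22, and divided knockdown libraries gave 3805 and 3407, 3114 and 2584, and 26 and 62. For genes that rose and fell again these were 2066, 1636 and 145 if independent, and 4430 and 4270, 3544 and 3431, and 60 and 177 divided. Rescue and control effects, both against knockdown, correlated at 0.90, 0.83 and 0.10 in the same order (simulated 0.47, 0.41 and 0.44), with covariances of 1.199, 0.998 and 0.04 against 0.017 simulated. With divided libraries the correlations were 0.88 and 0.86, 0.79 and 0.81, and 0.22 and -0.09. The simulated data hold no effects, so a simulated r cannot be set directly against an observed one. An observed r below it does not mean that effects are less alike than by chance.

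All rescues share the knockdown libraries, which makes effects alike. As above, the simulated r values hold no effects and cannot be set directly against the observed ones. Across genes, which are not independent replicates, wild-type and mut9 effects correlated at r = 0.90, against 0.44 in data simulated without any effect and 0.88 and 0.84 when the knockdown libraries were divided between the effects. Their covariance was 0.827 against 0.017 simulated. Both rose for 3393 genes (1227 if independent, 2691 and 2816 with divided libraries) and both fell for 4009 (1487, 3369 and 3269). Wild-type and delta 22 effects correlated at r = 0.13 (simulated 0.47), and at -0.08 and 0.23 with divided libraries. Their covariance was 0.04 against 0.017 simulated, a difference of 0.023, against 0.81 for wild type and mut9. Both rose for 109 genes (119 if independent, 73 and 29 divided) and both fell for 209 (131, 171 and 61). For mut9 and delta 22 the correlation was 0.18 (simulated 0.41, divided -0.08 and 0.32), with a covariance of 0.051 against 0.017.

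Rescue was also measured in libraries not used to pick the genes. Genes were chosen in batches 1 and 2 and measured in batches 3 to 5, where the label of the replicate is that of the batch. For 1303 genes raised by wild type, mut9 reached 0.917 ± 0.098 of the wild-type effect (mean ± SD of 3 batches) and delta 22 -0.048 ± 0.129 (2 batches). For 2586 genes lowered by wild type, mut9 reached 0.868 ± 0.117 and delta 22 0.034 ± 0.027. In batches 3, 4 and 5 the mut9 fractions of these genes were 0.956, 0.735 and 0.914. The median log2 changes were -1.193, -1.196 and -1.118 with mut9 and -1.249, -1.627 and -1.223 with wild type. The higher fractions thus came where the wild-type effect was smaller. Of the difference between control and knockdown, wild type reached 0.661 ± 0.017 for 1793 genes that fell with knockdown and 0.58 ± 0.021 for 3349 that rose (2 batches). Mut9 reached 0.635 ± 0.053 and 0.551 ± 0.02. These fractions come from batches 3 and 5, the held-out batches with a control library. There the median wild-type changes were log2 0.831 and 0.876 for the first class, and -1.018 and -0.991 for the second. In batch 4 they were larger, 0.995 and -1.314. The fractions can thus understate wild type, and the closeness of mut9 rests on batches with the smaller wild-type effect. The direction was that of wild type for 97.4% and 96.6% of genes with mut9, and for 46.9% and 54.7% with delta 22. Fractions of the difference between control and knockdown moved with the settings, from 0.513 to 0.796 for wild type in the first class, with 0.628 without knockdown replicate 2. Delta 22 reached 0.005 of the lowered class without wild-type replicate 1.

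**Figure D4:**
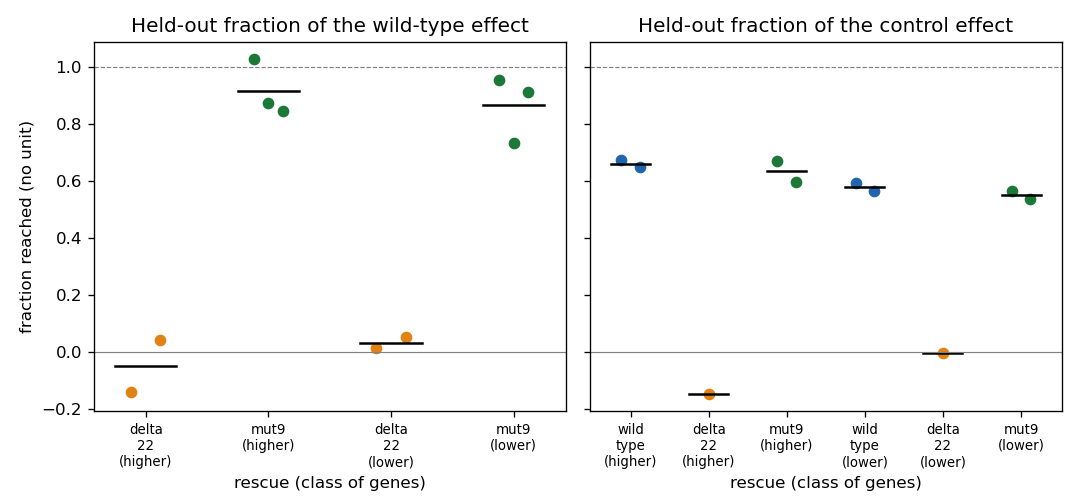
Fraction of the wild-type effect, or of the difference between control and knockdown, reached by each rescue per held-out batch, with points for batches and bars for means. Mut9 has mean fractions of the wild-type effect of 0.917 and 0.868, with 0.735 in batch 4 for lowered genes. Delta 22 lies near 0 (-0.048 and 0.034).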

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

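Values of FLI1, EWSR1, the list means and the genes named in the text were searched, in each group of 4 or 5 libraries, for a library whose gap to its nearest neighbour takes up most of the group's range. Chance alone gives about 1 such case in 20 groups, and 32 of the groups tested (4.5%) had one. Apart from the depth test, the tests of this part were chosen after the result was seen.

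Wild-type replicate 3 had 7 of the 32 cases. It was highest in its group for IRF1 (10.91 against 8.91 to 9.43, gap ratio 0.741), MX2 (11.35 against 4.87 to 6.21, 0.792), IFI27 (11.73 against 5.31 to 7.06, 0.728), B2M (16.77 against 15.98 to 16.08, 0.866), SPX (0.717) and CFI (0.738), and lowest for CAV1 (0.765). Control replicate 1 had 5: highest for LIPI (0.931) and the ribosomal protein list (0.928), lowest for IGFBP6 (0.84), TM4SF1 (0.933) and the histone list (0.862). Delta 22 replicate 3 was lowest for COL6A1 (0.847), COL6A2 (0.925), WNT5B (0.896) and the mesenchymal list (0.848) and highest for HMGA2 (0.875), and delta 22 replicate 1 was lowest for LOX (0.848) and PMP22 (0.928). Knockdown replicate 3 was lowest for SNAI2 (0.77) and highest for MX2 (0.756) and FZD4 (0.762). Single cases were PLD2 (0.818, wild-type replicate 1), CALCB (0.814) and LGR5 (0.772) in wild-type replicate 2, ITGB1 (0.765, wild-type replicate 5), NKD2 (0.863, control replicate 2), CAV2 (0.879, control replicate 5), P4HA2 (0.865) and the housekeeping list (0.896) in knockdown replicate 1, YWHAZ (0.715, knockdown replicate 2) and ZNRF3 (0.714, knockdown replicate 5).

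The interferon genes of wild-type replicate 3 had a mean of 11.91, within the knockdown range (11.81 to 12.86), and its NF-kB genes 10.54, above the other wild-type libraries (7.46 to 8.43) and below all knockdown libraries (10.76 to 12.78). RNA of knockdown cells in this library would raise all genes high after knockdown alike, but 574 other such genes gave a median share of 6.1% (quartiles 0.8 to 17.9%) against 65% (29 to 82.8%) for the 41 list genes. A batch 3 effect alike in all groups is argued against by the excess of replicate 3, 2.97 log2 here and at most 1.03 elsewhere, a gap of 1.94. Replicate 3 is still highest in 4 groups, so a smaller shared part stays open. An interferon response of these cells, for whatever reason, was not tested.

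Most genes under wild-type control did not recover with delta 22, which shared 2% of the raised and 3.6% of the lowered genes. ATF4 targets were an exception in part. Their list mean was 11.41 to 12.06 with delta 22, 11.14 to 11.87 with wild type and 12.11 to 12.43 after knockdown. The explanations below concern the genes that did not recover. Too little transcript is argued against by FLI1, 0.8 log2 above wild type (SD between delta 22 libraries 0.23). Empty-vector libraries under this label are argued against by a gap of 1 log2 between the lowest delta 22 and the highest knockdown value of FLI1. Low depth is argued against by genes with a mean of at least 1000, where the largest held-out fraction was 0.099 (mut9 0.912 and 0.819 on average). The level of delta 22 protein was not measured and stays open beside a loss of function, and FLI1 reads do not tell the construct from the endogenous gene.

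Collagen and matrix genes were higher with mut9 than with wild type. The absence of mut9 from batches 1 and 2 is argued against by a mean within-batch difference of 0.78 log2 (0.54, 1.06 and 0.75). The recovered fractions were 0.52 for this list and 1 for the activated list, a mean gap of 0.48 with the smallest at 0.42. They cannot decide whether mut9 is weaker on all targets alike. The list was chosen for its difference between mut9 and wild type in these same libraries, which lowers its fraction in advance. Genes picked in batches 1 and 2 by the wild-type effect gave mut9 fractions of 0.917 (raised) and 0.868 (lowered). That matrix genes need more EWS/FLI than activated genes, with FLI1 at 10.23 here and 10.47 with wild type, remains an untested hypothesis beside a difference in what mut9 can do.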

How the results depend on the processing

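Directions of the named genes held in all settings run, with GAPDH as the exception: quantile scaling gave 0.08 for the wild-type rescue and -0.02 for delta 22 against wild type. Sign changes of genes called in neither fit are not counted. Alternatives with a pseudocount, edgeR and DESeq2 were not run, since whole reads cannot be recovered from the deposited values, nor was a search for GGAA repeats, which needs a genome sequence. Depth is known in order only, judged from the floor of the lowest values, with rank 1 the deepest of 21. Delta 22 libraries rank 12 to 21 and knockdown libraries 11 to 20. Mut9 libraries rank 3 to 7, wild-type libraries 1 to 13 and control libraries 2 to 16. Depth thus differs in part between these groups, and low values are shrunken, so losses among weak genes cannot be judged.

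The count for the delta 22 rescue was 811, and 1292 with a replicate block or 262 from the compared groups only, a fit with fewer libraries. For mut9 against wild type it was 3390, and 5234 with array weights or 1745 in batches 3 to 5 only, an alternative added later that shared 1641 genes. Activated genes shared with delta 22 were 109, and 56 without a filter, 194 with a block and 28 from the compared groups. Repressed ones were 209, and 138 at a mean of at least 100, 352 with a block and 97 from the compared groups. Activated genes weaker with mut9 went from 977 to 1660 with quantile scaling. Held-out fractions for genes that fell with knockdown were 0.661 with wild type, and 0.642 without a filter, 0.611 at a mean of at least 100, 0.578 with quantile scaling, 0.513 without a minimum fold and 0.796 with selection in batches 3 to 5. For genes that rose they were 0.58, and 0.615 with quantile scaling and 0.762 with selection in batches 3 to 5. With mut9 the former were 0.635, and 0.548 with quantile scaling and 0.495 without a minimum fold, and the latter 0.551, and 0.498 at a mean of at least 100, 0.598 with quantile scaling and 0.526 without a minimum fold. Of the wild-type effect, mut9 went from 0.917 to 0.818 and delta 22 from 0.034 to -0.005 without a minimum fold. Beyond the smaller fits and filters, the cause was not tested.

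An estimated correlation left 1 list of 21 for the knockdown, 1 of 18 for wild type against control, and 0 of 17, 7, 17, 15, 12 and 16 for the wild-type, delta 22 and mut9 rescues, delta 22 against wild type, mut9 against wild type and mut9 against delta 22. The test uses camera, and the counts at the preset correlation stand beside each 0. The test fry called 2 lists for the delta 22 rescue, 1 of them among the 7, and over all comparisons it gave 38 stronger and 12 weaker list calls. The replicate block changed 10 list calls, 9 weaker and 1 stronger, and 17 calls of named genes, 10 weaker and 7 stronger. For named genes the compared groups gave 41 weaker and 2 stronger calls, no filter 25 and 1, quantile scaling 17 and 7, and rescaling by trimmed means 4 and 2. Single libraries left out gave 273 weaker and 16 stronger. For the delta 22 rescue they gave 383 to 857 genes and 4 to 8 lists, and for mut9 against wild type 1723 to 3572 genes. Genes shared with delta 22 ranged from 53 to 122 activated and 119 to 290 repressed, and genes weaker with mut9 from 513 to 1025 activated and 788 to 1622 repressed. The held-out fraction of wild type for genes that fell ranged from 0.628 to 0.673, and that of delta 22 for genes lowered by wild type from 0.005 to 0.053.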

Other observations

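Several groups of genes moved without forming a clear list result. Endothelial markers rose after knockdown (5 higher and 1 lower of 7, camera adjusted p = 0.0322, and adjusted p = 0.225 with an estimated correlation), with the receptor gene KDR (4.01 ± 0.30), ROBO4 (4.87 ± 0.39) and TIE1 (4.49 ± 0.36), and fell with wild type (2 higher and 5 lower of 7, camera adjusted p = 0.0637) and mut9 (1 higher and 5 lower of 7, camera adjusted p = 0.0265, and adjusted p = 0.277 with an estimated correlation). The wild-type call was gained without knockdown replicate 5 (0.0482) or wild-type replicate 5 (0.0474). Wnt genes split: WNT5B (5.64 ± 0.18), DKK3 (6.74 ± 0.27) and DKK1 rose after knockdown and NKD2, ZNRF3, LGR5, DKK2 and FZD4, named after their values were seen, fell (12 higher and 5 lower of 20, camera adjusted p = 0.0446, and adjusted p = 0.1 with an estimated correlation). With wild type WNT5B (-3.91 ± 0.17) fell and DKK2 (4.51 ± 0.28) rose (4 higher and 11 lower of 20, camera adjusted p = 0.0324, and adjusted p = 0.0862 with an estimated correlation). Hedgehog genes split as well (3 higher and 5 lower of 12, camera adjusted p = 0.385): GLI1 (-3.77 ± 0.19), PTCH1 (-1.78 ± 0.11) and GAS1 (-2.01 ± 0.21), a coreceptor, fell and BOC (2.74 ± 0.26) rose. Insulin-like growth factor genes rose in part after knockdown (10 higher and 4 lower of 16, camera adjusted p = 0.0366, and adjusted p = 0.1 with an estimated correlation), as did FOXO targets (12 higher and 4 lower of 17, camera adjusted p = 0.0397, and adjusted p = 0.322 with an estimated correlation), a call lost for FOXO targets without knockdown replicate 1 (0.0543). Meanwhile IRS2 (-1.39 ± 0.10), an insulin receptor substrate in both lists, fell. Epithelial markers gave 4 higher and 0 lower of 9, camera adjusted p = 0.125, with the claudin gene CLDN4 (3.75 ± 0.31) higher. Immune cell markers gave 4 higher and 0 lower of 5, camera adjusted p = 0.0746, with CD14 (1.97 ± 0.30) higher.

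Hypoxia and glycolysis genes split after knockdown (12 higher and 9 lower of 23, camera adjusted p = 0.507): ADM (4.91 ± 0.25) and NDRG1 (5.18 ± 0.29) rose and the enolase gene ENO2 (-1.37 ± 0.14) fell. With wild type they fell (0 higher and 14 lower of 23, camera adjusted p = 0.00224, and adjusted p = 0.148 with an estimated correlation), with VEGFA (-1.41 ± 0.12), the vascular growth factor, and quantile scaling gave 5 members higher. They stayed higher in part with mut9 than with wild type (8 higher and 0 lower of 23, adjusted over the list alone 9 and 0, camera adjusted p = 0.000103, and adjusted p = 0.185 with an estimated correlation), with the glucose transporter gene SLC2A3 (0.96 ± 0.18). Glutathione and redox genes gave 7 higher and 6 lower of 17, camera adjusted p = 0.74 after knockdown. For mut9 against wild type they gave 7 higher and 0 lower of 17, camera adjusted p = 0.0271, and adjusted p = 0.638 with an estimated correlation. GSTM3 (0.71 ± 0.16), whose reads can be shared with its relatives, was higher there. The list lost its call without wild-type replicate 3 (0.0665) or 5 (0.0502) or mut9 replicate 3 (0.101). Targets of p53 gave 10 higher and 5 lower of 20, camera adjusted p = 0.222, with CDKN1A higher and FDXR (-1.36 ± 0.16) lower. Mitochondrially encoded genes, whose reads can also map to nuclear copies, gave 1 higher and 2 lower of 15, camera adjusted p = 0.765 after knockdown. For mut9 against wild type they gave 0 higher and 4 lower of 15, adjusted over the list alone 0 and 9, with MT-ND3 (-0.43 ± 0.10). Camera adjusted p was 8.96e-05 there, and adjusted p = 0.46 with an estimated correlation. Housekeeping genes were not steady (4 higher and 9 lower of 15, camera adjusted p = 0.281), with YWHAZ (1.12 ± 0.09) and B2M (1.21 ± 0.15) higher and PGK1 (-0.45 ± 0.06) lower. Cell cycle genes were called for mut9 against wild type with 0 higher and 2 lower of 29, adjusted over the list alone 0 and 0 (camera adjusted p = 0.00968, and adjusted p = 0.745 with an estimated correlation) and cholesterol genes with 3 higher and 0 lower of 24 (camera adjusted p = 0.0271, and adjusted p = 0.748 with an estimated correlation). The former was lost without mut9 replicate 5 (0.157) and the latter without wild-type replicate 1 (0.0722) or 5 (0.144) or mut9 replicate 3 (0.317).

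Other splits of the compared libraries were fitted as well, with tests chosen before the data were examined. With pairing left aside, 1 split, the real one, reached the count of genes in each of the 8 comparisons. Splits numbered 100, 56 with mut9 and knockdown or wild type, and 35 for mut9 against delta 22. The real count and the highest of the other splits were 12537 and 10684 for the knockdown, 11154 and 5760 for the wild-type rescue, 811 and 505 for the delta 22 rescue, 8759 and 3079 for the mut9 rescue, 11045 and 9252 for delta 22 against wild type, 3390 and 888 for mut9 against wild type, 8885 and 6173 for mut9 against delta 22, and 7135 and 5053 for wild type against control. Batch numbers pair the libraries. Among splits that part as many pairs as the real one the highest counts were 10684, 5645, 2, 4, 1842, 1, 4733 and 4560 in the same order. There were only 13, 11, 12, 7, 12, 7, 11 and 14 such other splits, too few for a share under 0.05. With pairing kept, chance can thus not be excluded for any of these counts. High counts came from splits that keep most libraries of 1 group together, such as knockdown replicate 4 with all control libraries.

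Counts of gene lists called by camera are another matter. With pairing left aside, 1 of 100 splits, the real one, reached the 21 lists of the knockdown, and the highest other split called 19. With pairing kept, chance cannot be excluded there. The 13 other splits that part as many pairs reached 19 lists, and they are too few for a share under 0.05. For the rest chance cannot be excluded even with pairing left aside. As many lists were called in 14 of 100 splits for the wild-type rescue (17 real, 19 highest other), 64 of 100 for the delta 22 rescue (7, 17, and 4 real without knockdown replicate 5), 7 of 56 for the mut9 rescue (17, 19), 38 of 100 for delta 22 against wild type (15, 19), 20 of 56 for mut9 against wild type (12, 18), 7 of 35 for mut9 against delta 22 (16, 18) and 13 of 100 for wild type against control (18, 21). Camera with its preset correlation called a median of 8 to 14 lists in the other splits, and the cause was not tested. The other splits exchange only some libraries and keep part of the real difference. For the wild-type rescue, the split with 19 lists put wild-type replicates 1, 2, 3 and 5 with knockdown replicate 3. Outside the knockdown such splits cannot decide whether chance gave the number of lists, which is therefore not used as evidence. For the knockdown that number is evidence only with pairing left aside, and the libraries do show pairing. Statements on lists describe counts of members, which can be correlated and are not independent evidence either. Such counts are to be read beside the genes called among all 18040. These were 12537 for the knockdown and 11154, 811 and 8759 for the wild-type, delta 22 and mut9 rescues. They were 11045 and 3390 for delta 22 and mut9 against wild type, 8885 for mut9 against delta 22 and 7135 for wild type against control.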
